A study of Mus musculus with 6 samples.

How the data were processed

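RNA of cultured mouse lymphatic endothelial cells was measured on 6 Affymetrix arrays of 45101 probe sets. Per the labels' protocols, 50 ng of total RNA per array was biotin-labelled with a kit that amplifies small amounts. Tumours were digested with collagenase, elastase, hyaluronidase and DNase and cultured, contaminating tumour cells were lifted with EDTA, and the adherent endothelial cells were detached with accutase. The text on the tumours then runs into that on skin, so the later steps for the tumour cells are not clear from it. Skin was treated with dispase, the epidermis was removed and the dermis scraped. Cells from both sources grew in an endothelial medium on gelatin before selection with LYVE-1 antibodies on magnetic beads. The labels give no batch, scan date or animal for any array, and the growth text of tumour replicates 2 and 3 leaves out the incubator details that the others have.

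The deposited values are log2 expression per probe set. Per the submitters' processing notes, RMA and GCRMA were used, with no versions, role or order, and which of them made the values is not stated. Both correct the background, normalize between arrays and summarise the probes of a probe set. Control probe sets for absent bacterial RNA had a median of 2.56 to 2.77 per array. GCRMA draws dim signals towards a floor, so differences of dim genes are hard to interpret and differences against the floor can look larger than with other methods. The array distributions were nearly but not exactly equal. No scanner files were used here.

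Probe sets were named through GEO's platform annotation, which is old, and symbols were updated through Entrez identifiers in a RefSeq gene table of assembly GRCm38.p6. Of the 45101 probe sets 34945 had 1 gene, 932 several, 9160 none listed and 64 were controls. No symbol changed in the update, and 204 of the probe sets with 1 gene have an identifier that is not in the table. Probe sets with several genes or none were counted but not named. Genomic positions were not used except for which genes neighbour Mycn.

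The comparison of 3 tumour with 3 normal arrays used R 4.3.3 and limma 3.58.1 (lmFit and eBayes, without trend or robust estimation). Probe sets with a mean log2 value above the 40th percentile (2.71) were kept, which left 27022. For genes with several probe sets the brightest by mean over the 6 arrays was used, which gave 12955 genes. A gene passed with a Benjamini-Hochberg adjusted p under 0.05, two-sided, and the size threshold was 2-fold. The eBayes prior had 1.61 degrees of freedom beside 4 residual ones. A group was called at background where each of its arrays lay at or below that array's highest value among 27 control probe sets for absent bacterial RNA (3.40 to 3.71). The fold change of such a gene was computed against that highest value and given as a lower bound. Where only some arrays of a group were at background, each such value was raised to the limit of its array for the bound, a step added after the data were seen. With 3 arrays against 3, an exact permutation test of a single gene cannot give a p under 0.1, so none was run.

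Before the data were examined, 23 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists held 640 entries, of which 609 are on the array under a single gene, 2 of these through a synonym. Lists with at least 5 measured genes, apart from the sex-linked genes, were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 20 lists. Genes were also adjusted over each list alone. The rule named up to 12 genes per direction past the threshold with separated groups, for each list up to 2 members per direction past the threshold or else the 2 with the smallest p, always Lyve1, Prox1, Pdpn, Flt4, Pecam1, Cdh5, Ptprc, Cd68, Pdgfra and Pdgfrb, the sex-linked genes, and the control probe sets for Gapdh and actin. Other list members, such as Thy1, Fn1, Tnc, Lama4, Col3a1, Col6a1, Timp1, Adamts4, H2-K1, Psmb8, Tap1, Tap2, Cd200, Cd274, H2-Eb1 and Pkp1, were named after their values were seen.

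The steps were tested on simulated data with the means and spreads of the 12955 genes. Of genes changed by 1, 2, 4 and 8 log2 units, 44%, 68%, 86% and 100% were recovered, and 11 of 160 calls were unchanged genes. The changed genes were drawn at random and kept their own spread, so the shares do not hold for genes with a wide spread. In the real data Pdgfra, at -5.03 with an SD of 1.42 on the normal arrays (n = 3), did not pass the test. Camera recovered a list raised by 1 log2 unit and called 0 of the others. The simulated genes were drawn independently of each other, so this does not test camera on genes that vary together. The alternatives were no filter or a 60th percentile filter, quantile normalization, median centring, an intensity trend with robust variance, array weights, the mean of a gene's probe sets, leaving out probe sets prone to cross-hybridization, the replicate number as a block, and leaving out each array. A change of pseudocount did not apply, since the values were already on a log2 scale.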

Results

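The expression profiles of cultured mouse lymphatic endothelial cells (LEC) from a metastatic tumour and from normal skin were compared on Affymetrix arrays. Tumour LEC came from fibrosarcomas grown in C57BL/6 mice from T241 cells, a mouse fibrosarcoma line, that carried VEGF-C, a growth factor for lymphatic vessels, and green fluorescent protein. Normal dermal LEC came from tail skin of female mice of the same strain, aged 8 weeks. Per the labels, both were purified with antibodies to LYVE-1, a hyaluronan receptor on lymphatic endothelium, after culture. Their text is not clear on the later steps for the tumour cells. Each group had 3 arrays. The titles of the tumour arrays speak of tumour cells, whereas their source descriptions name the endothelial cells isolated from the tumours, and the second description is followed here. The labels do not say whether the replicates were separate cultures or animals, so the p-values measure only the spread between these arrays. The number of arrays limits the precision of every value.

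The median log2 value of an array lay between 2.99 and 3.02 on 5 arrays and was 3.15 in tumour replicate 3. Control probe sets for absent bacterial RNA had a median of 2.77 on that array and of 2.56 to 2.61 on the other 5. Signal from the 3 prime end of Gapdh exceeded that from its 5 prime end by 1.82 to 2.25 log2 units, with both groups inside that range. Across genes, which are not independent replicates, arrays of the same group correlated at 0.961 to 0.987 and arrays of different groups at 0.920 to 0.972. The first principal component held 55.7% of the variance and separated the groups, with normal replicate 1 and tumour replicate 3 at its ends.

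With all 6 arrays, most of the genes that passed the test between tumour and normal LEC were lower in the tumour cells. With any 1 tumour array left out, the few genes that passed were split about evenly. Mycn, a transcription factor of the MYC family, read at background in normal LEC and at 13.39 ± 0.34 (SD, n = 3) in tumour LEC. Col1a2, a chain of type I collagen, went the other way, from 12.56 ± 1.50 in normal LEC to 3.18 ± 0.43 in tumour LEC (SD, n = 3). Genes of antigen presentation, of the interferon response and of endothelial cells in general were higher as groups in tumour LEC, and genes of fibroblasts, extracellular matrix, proteases and cell division were lower. These 7 calls held with a preset correlation between genes only, with adjusted p = 0.755 for each with an estimated correlation and 0 lists past the threshold by limma fry. None of the lymphatic markers passed the test.

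Of 12955 genes tested, 28 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 6 higher and 22 lower in tumour LEC, and all 28 differed at least 2-fold. Without adjustment, 2007 genes had a p under 0.05. The 3 tumour arrays did not overlap the 3 normal arrays for 4203 genes, 32.4% of those tested against an expected 10% by chance. Of these, 2703 were higher and 1500 lower in tumour LEC. The 4203 genes include 1182 at background on all arrays, 1176 of them higher in tumour LEC, where the background itself read higher. Of the 11105 genes above background on some array, a set chosen after the data were seen, 3021 (27.2%) separated the groups, 1527 higher and 1494 lower. Genes vary together across arrays, so a share can lie far from 10% by chance. These shares were not computed for other splits of the arrays. By probe set, 60 of 27022 passed, 13 higher and 47 lower, and 11 of them have no single gene name. The count of genes moved when single arrays were left out, a step that also lowers the power of the test, and the cause was not tested. The count was 82 without normal replicate 1 (7 higher, 75 lower), 20 without normal replicate 2 (1, 19) and 6 without normal replicate 3 (1, 5). For the tumour arrays it was 9 without replicate 1 (4 higher, 5 lower), 11 without replicate 2 (5, 6) and 4 without replicate 3 (2, 2). It was 10 with no filter on low values and 385 with arrays weighted by quality, and Mycn alone among the named genes passed in all 15 alternative settings.

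Mycn rose by 10.47 log2 units (SE 0.19, adjusted p = 8.66e-05), at least 990.5-fold above background. Its probe sets were far apart: the brightest gave this value and the others 2.12 and 0.13. Nts, the precursor of the peptide neurotensin, rose 18.1-fold, from 7.26 ± 0.54 to 11.43 ± 0.68 (SD, n = 3, adjusted p = 0.0490). Sema7a, a membrane-anchored semaphorin, rose 8.79-fold (log2 difference 3.14, SE 0.27), Pawr, a regulator of apoptosis, 4.42-fold (2.14, SE 0.20) and Pde8a, a cyclic AMP phosphodiesterase, 2.12-fold (1.08, SE 0.11). H2-Q5, of the MHC class I family, was at background in normal LEC and rose at least 10.4-fold. Its other probe set differed by 0.13, and the family has near-identical genes that probes do not always tell apart.

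The 22 genes that fell included adhesion molecules, receptors and secreted proteins detected on the normal arrays. Of these genes 19 were highest in normal replicate 1 among the normal arrays, where fibroblast markers were also highest (median deviation 3.86). For 16 of the 28 changed genes the tumour arrays were at background, so their fold changes are lower bounds. S1pr3, a receptor for sphingosine 1-phosphate, was at least 95.9-fold lower in tumour LEC (log2 difference -8.24, SE 0.64). Pcdh19, a protocadherin, was at least 53.3-fold lower, and Cdh2 or N-cadherin at least 38.3-fold lower (-5.86, SE 0.41, adjusted p = 0.0202). Sema3c, a secreted semaphorin, was at least 37.0-fold lower, and Prkg2, a cyclic GMP-dependent kinase, at least 42.6-fold lower (-6.48, SE 0.32, adjusted p = 0.00611). Msln, which encodes mesothelin, at least 24.0-fold lower, had the smallest adjusted p of the lower genes named here (-5.04, SE 0.22, adjusted p = 0.00402). Rpl39l, a ribosomal protein paralogue, Nrn1 or neuritin and Grem1, an antagonist of bone morphogenetic proteins, were at background in tumour LEC too, and lower by at least 52.4-fold, 19.7-fold and 13.7-fold. Emp3 (-6.28) and Perp, a desmosome-associated protein (-5.30), kept some signal there, and Crabp1, which binds retinoic acid, was at background on 1 tumour array and at least 40.6-fold lower. Col1a2 was at background on 2 of the 3 tumour arrays and, with those values raised to the background limit, at least 492-fold lower (adjusted p = 0.0276). Its other probe sets differed by -8.26 and, with little signal in either group, -0.59.

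**Figure D1:**
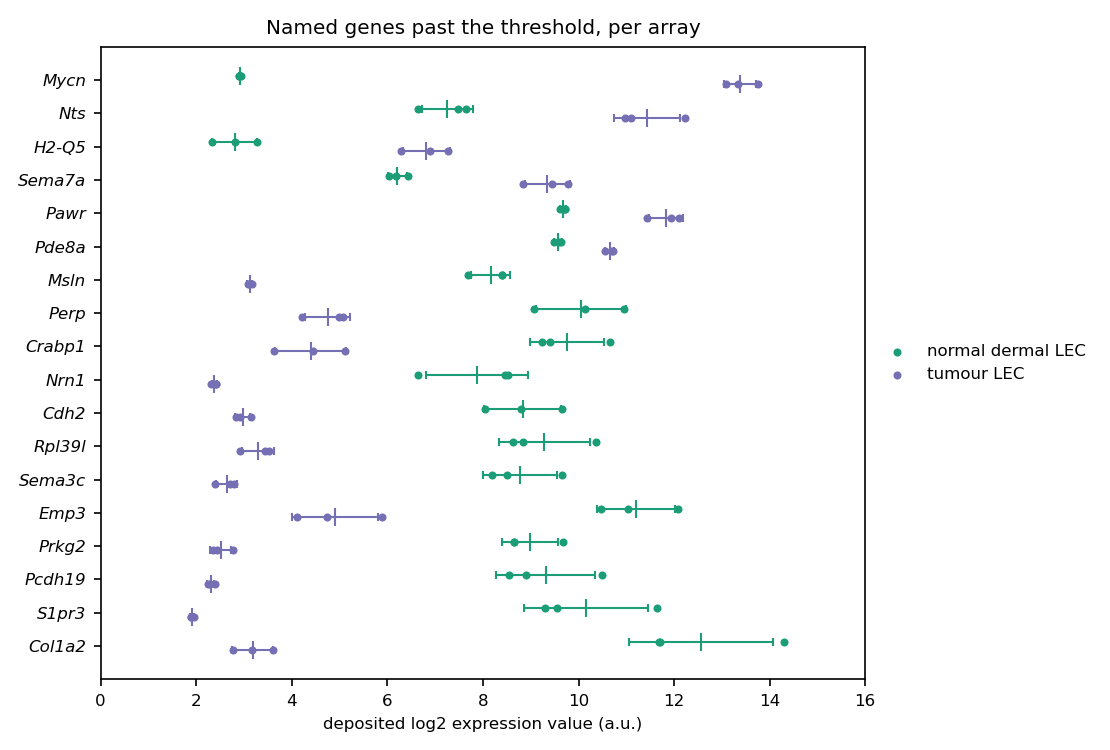
Deposited log2 expression value on each array (points) for 18 named genes past the threshold, with the mean (tick) and SD (bar) of the 3 normal and the 3 tumour arrays. Mycn lies near 2.91 on the normal arrays and near 13.39 on the tumour arrays, and Col1a2 shows the opposite order.

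No lymphatic identity gene passed the test. Lyve1, whose product was used for selection, read 14.60 ± 0.43 in tumour LEC and 14.00 ± 0.34 in normal LEC (SD, n = 3), a difference of 0.60 (SE 0.28, adjusted p = 0.375). Prox1, the master regulator of lymphatic fate, differed by 0.40 (SE 0.33), Pdpn or podoplanin by 0.09 (SE 0.23) and Flt4, the VEGF-C receptor, by 0.03 (SE 0.25). None of the 19 measured genes of this list passed, over all genes or adjusted over the list alone, although the groups did not overlap for 2 higher and 3 lower genes, and the list's median difference was 0.19 (limma camera, adjusted p = 0.602). Leaving out single arrays moved it between 0.034 and 0.53, and none of these passed. The members with the smallest p were Foxc2, a transcription factor of lymphatic valves, at -1.74 (SE 0.36), and Tbx1 at 1.36 (SE 0.39). The signs for Prox1, Pdpn and Flt4 changed in some alternative settings.

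The pan-endothelial list was higher in tumour LEC, with a median difference of 0.98 over 26 genes, 23 of them positive (camera, adjusted p = 1.16e-05). With an estimated correlation between its genes its adjusted p = 0.755, the value shared by all 7 lists named as higher or lower here. None of its genes passed over all genes, and 5 passed adjusted over the list alone, among them Ets1, an endothelial transcription factor, at 1.04 (SE 0.15), and Eng, a TGF-beta co-receptor, at 1.70 (SE 0.38). Cdh5, the cadherin of endothelial junctions, differed by 1.01 (SE 0.45) and Pecam1 by 1.44 (SE 0.69). Of the 26 genes, 17 were lowest in normal replicate 1, the array with the highest fibroblast genes, and without it the median was 0.61. Blood vascular genes did not pass as a group, with a median of 0.03 over 21 genes (camera, adjusted p = 0.637). Among them Unc5b, a netrin receptor, differed by 1.49 (SE 0.24) and Mgp, an inhibitor of calcification and at background on 2 tumour arrays, was at least 62.3-fold lower, both past the threshold adjusted over the list alone.

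Genes of antigen presentation and immune inhibition were higher in tumour LEC as a group. The median difference over 19 genes was 1.23 and 17 were positive (camera, adjusted p = 1.04e-07). With an estimated correlation the adjusted p = 0.755, and 12 genes passed adjusted over the list alone while none passed over all genes. H2-D1, a classical MHC class I heavy chain, read 13.22 ± 0.32 in tumour LEC (SD, n = 3), higher by 2.22 (SE 0.26, adjusted p = 0.0577), and H2-K1 differed by 2.05 (SE 0.30). Psmb9 and Psmb8, subunits of the immunoproteasome, differed by 3.23 (SE 0.46) and 3.42 (SE 0.78), and the peptide transporters Tap1 and Tap2 by 2.17 (SE 0.49) and 1.80 (SE 0.36). Cd200, a ligand that restrains myeloid cells, differed by 2.37 (SE 0.58). Cd274, which encodes PD-L1, differed by 0.77 (SE 0.32) and passed neither threshold. MHC class II genes were dim, with H2-Eb1 at 4.65 in tumour LEC and 3.58 in normal LEC.

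The interferon response list, which shares 3 measured genes with the antigen presentation list, had 31 of 32 genes higher in tumour LEC and a median difference of 1.27 (camera, adjusted p = 7.45e-10, and adjusted p = 0.755 with an estimated correlation). Adjusted over the list alone 4 genes passed, Psmb9, Psmb8, Tap1 and Oas1a, the last an activator of RNase L that differed by 4.44 (SE 0.77). The normal arrays were uneven here: the list's median deviation from the gene means was -1.93 in normal replicate 2, -0.70 in normal replicate 1 and 0.10 in normal replicate 3, against 0.21 to 1.50 on the tumour arrays. It was highest in tumour replicate 1, where leukocyte markers were also highest (1.97), and without that array the median difference was 0.85.

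Fibroblast genes were far lower in tumour LEC. Of the 24 measured genes of the fibroblast or fibrosarcoma list 23 were lower, with a median difference of -3.62 (camera, adjusted p = 6.69e-15, and adjusted p = 0.755 with an estimated correlation). Col1a2 passed over all genes, and adjusted over the list alone 19 genes were lower and 1, Thy1, higher by 0.67 (SE 0.21). Pdgfra and Pdgfrb, the receptors for platelet-derived growth factor on mesenchymal cells, differed by -5.03 (SE 0.75, adjusted p = 0.0828) and, with 2 tumour arrays at background, by at least 39.5-fold (adjusted p = 0.0787). On the normal arrays 23 of the 24 genes were highest in normal replicate 1, where the median deviation from the gene means was 3.86, against 1.15 and 1.22 in normal replicates 2 and 3 and -1.99 to -1.67 on the tumour arrays. Pdgfra read 11.75 in normal replicate 1, 9.48 and 9.13 in the other normal arrays and 4.66 to 5.74 in tumour LEC.

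The extracellular matrix list, 9 of whose 51 measured genes are also in the fibroblast list, had a median difference of -1.06 (camera, adjusted p = 6.61e-04, and adjusted p = 0.755 with an estimated correlation). It went both ways, with 20 genes lower and 6 higher adjusted over the list alone, and its median was -0.25 without normal replicate 1. Among the lower genes were the collagens Col3a1, at background on 2 tumour arrays and at least 82.9-fold lower, and Col6a1 at -5.21 (SE 0.90). Fn1 or fibronectin at 0.70 (SE 0.15), Tnc or tenascin C at 2.35 (SE 0.37) and Lama4, a laminin chain of vascular basement membranes, at 1.45 (SE 0.30) were among those higher. The protease and inhibitor list had a median of -0.39 over 32 genes (adjusted p = 0.00815, and adjusted p = 0.755 with an estimated correlation), with 4 genes lower adjusted over the list alone. These were Mmp3 or stromelysin, at background in tumour LEC and at least 16-fold lower, Serpinf1, at background on 2 tumour arrays and at least 60.9-fold lower, Timp1 (-2.87) and Adamts4 (-1.40). Its adjusted p was 0.0711 without normal replicate 3 (median -0.62), 0.0561 without tumour replicate 2 (-0.34) and 0.0980 without tumour replicate 3 (-0.32), and without normal replicate 1 its median was -0.19. It was -0.15 with median centring, -0.16 with no filter on low values and -0.64 with array weights.

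**Figure D2:**
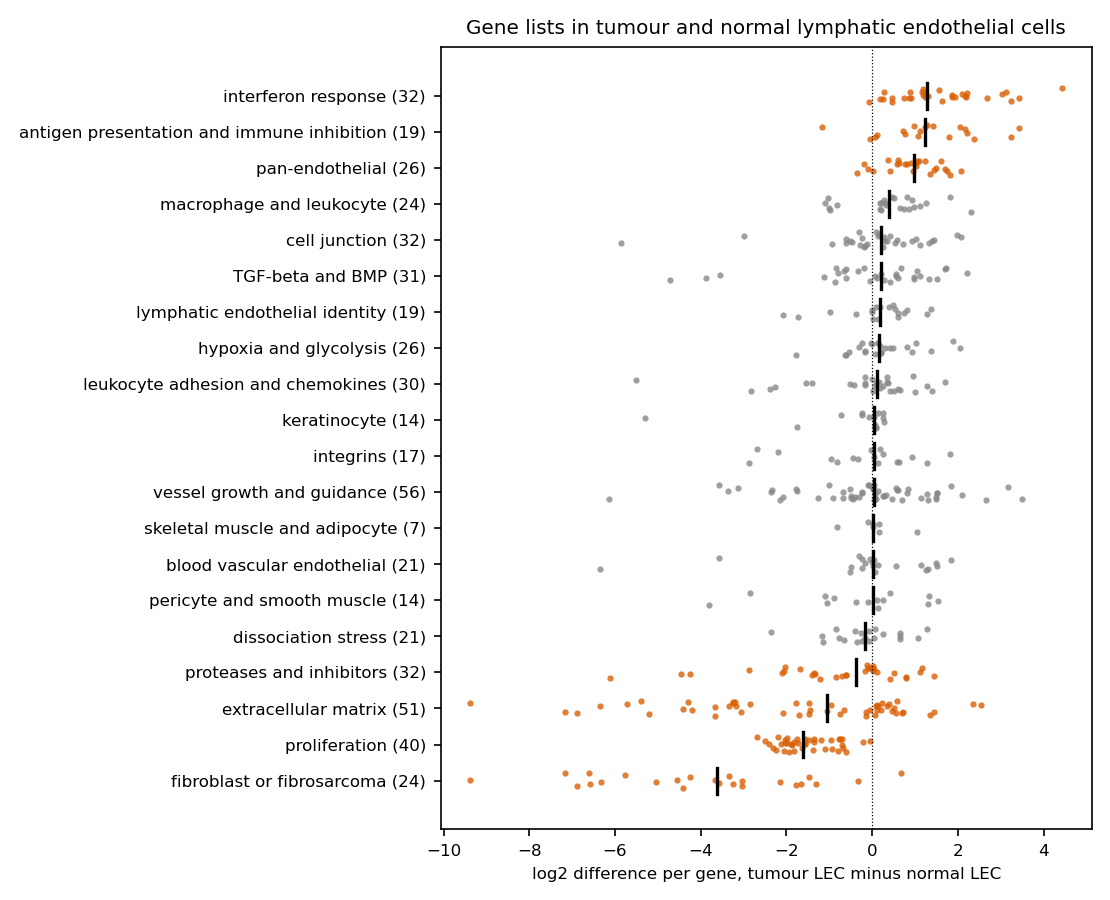
Log2 difference of each measured gene (points) in the 20 lists tested, tumour minus normal LEC, with the list median (bar) and the number of genes in brackets, in orange where camera's adjusted p with a preset correlation was under 0.05. The medians run from -3.62 for fibroblast genes to 1.27 for interferon response genes.

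All 40 measured proliferation genes were lower in tumour LEC, with a median difference of -1.61 (camera, adjusted p = 7.45e-10, and adjusted p = 0.755 with an estimated correlation). None passed singly, over all genes or adjusted over the list alone. Mcm7, part of the replicative helicase, differed by -1.47 (SE 0.48) and the cell cycle transcription factor E2f1 by -0.94 (SE 0.31). The shift was uneven between the tumour arrays, with median deviations from the gene means of -2.36 in tumour replicate 3, -0.59 in replicate 1 and 0.49 in replicate 2, the last close to the 0.47 of normal replicate 3. Without tumour replicate 3 the median difference was -0.81, and with arrays weighted by quality -0.56. Tumour replicate 3 also had the highest median value (3.15) and the highest median of the bacterial control probe sets (2.77) of all arrays.

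Markers of leukocytes were raised on a single tumour array. The macrophage and leukocyte list had a median difference of 0.39 over 24 genes and did not pass (adjusted p = 0.158). Its median deviation was 1.97 in tumour replicate 1, against -0.78 to 0.44 on the other 5 arrays, and without that array the median difference was -0.12. It passed without normal replicate 3 (0.80, adjusted p = 0.0123), without tumour replicate 2 (0.71, adjusted p = 0.0429) and without tumour replicate 3 (0.71, adjusted p = 0.00676). Ptprc, the leukocyte antigen CD45, read 5.92 in tumour replicate 1 and at most 3.36 elsewhere. Cd68, a lysosomal protein of macrophages, read 10.88 there, 7.90 and 4.82 in the other tumour arrays and 8.45 to 9.57 in normal LEC. Aif1 and Cx3cr1, the members with the smallest p, were at background on all arrays.

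**Figure D3:**
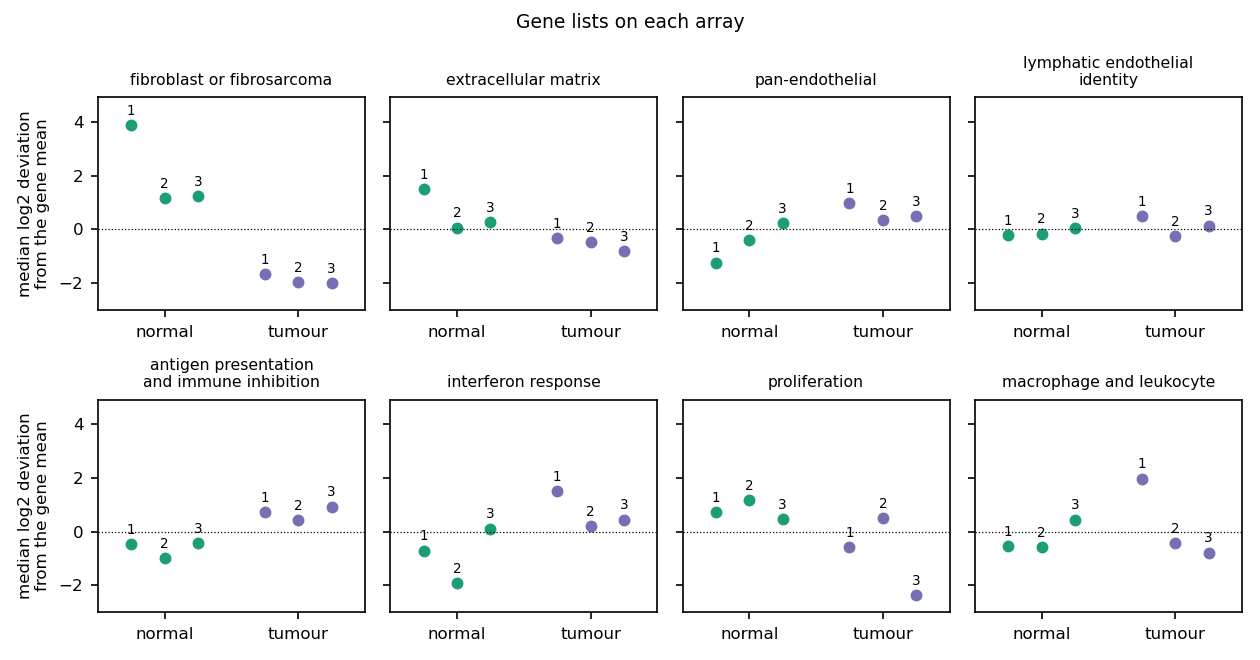
Median log2 deviation from the gene means for 8 gene lists on each array, with normal LEC in green, tumour LEC in purple and the replicate number beside each point. Fibroblast genes reach 3.86 in normal replicate 1, leukocyte genes 1.97 in tumour replicate 1 and proliferation genes -2.36 in tumour replicate 3.

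The other lists tested did not pass camera as groups. Cell junction genes had a median of 0.21 over 32 genes (adjusted p = 0.431), with Cdh2 lower over all genes and 5 genes higher and 3 lower adjusted over the list alone. Vessel growth and guidance genes had a median of 0.03 over 56 genes (adjusted p = 0.987), with Sema3c lower over all genes and 5 genes on each side adjusted over the list alone. TGF-beta and BMP genes had a median of 0.20 over 31 genes (adjusted p = 0.717), with Grem1 lower over all genes and again 5 genes on each side. Integrins had a median of 0.05 (adjusted p = 0.987), with Itga1 at 1.82 (SE 0.43) and Itgb3 at 1.28 (SE 0.31) and none past either threshold. Hypoxia and glycolysis genes had a median of 0.16 (adjusted p = 0.244), with Adm, the vasoactive peptide adrenomedullin, at 2.05 (SE 0.43) and P4ha1, a collagen prolyl hydroxylase, at 0.93 (SE 0.18) past the threshold adjusted over the list alone. Leukocyte adhesion and chemokine genes had a median of 0.12 (adjusted p = 0.731), with the neutrophil chemokines Cxcl5, at background in tumour LEC and at least 38.6-fold lower, and Cxcl1 at -2.37 (SE 0.40) past that threshold. Dissociation stress genes had a median of -0.16 (adjusted p = 0.637), with Ier3 at 0.66 and Egr2 at -2.36.

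Pericyte and smooth muscle genes had a median of 0.01 over 14 genes (adjusted p = 0.704), with Cspg4 or NG2, at background in tumour LEC and at least 8.84-fold lower, and Tpm2 at -2.85 (SE 0.59) lower adjusted over the list alone. Keratinocyte genes had a median of 0.05 (adjusted p = 0.602), with Perp lower over all genes and Pkp1, in addition, adjusted over the list alone, the latter at background on all tumour arrays and 1 normal array and at least 1.21-fold lower. Skeletal muscle and adipocyte genes had a median of 0.03 over 7 genes (adjusted p = 0.637), where Fabp4, also a gene of endothelial cells, differed by 1.04 (SE 0.43) and Acta1 was at background. The median was positive and the mean negative for the integrin, vessel growth, TGF-beta, blood vascular, leukocyte adhesion, pericyte and keratinocyte lists, and camera gave the direction as down for the last 2 of these. With 2 T lymphocyte genes and 3 melanocyte and Schwann cell genes measured, those lists were not tested: Cd4 differed by 0.28, Cd8a was at background, Mitf differed by -0.62 and Sox10 was at background. Xist, expressed from the inactive X chromosome, read 10.59 to 11.65 on all 6 arrays, and the Y-linked Eif2s3y was at background on all. Uty, also Y-linked, read 3.30 to 3.88 and was at background on all normal arrays and 2 tumour arrays. Only tumour replicate 3, at 3.88 against a limit of 3.71, lay above it.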

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

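Every alternative here but 1 was fixed before the data were examined. The count of changed genes moved by over 1.5 times in 10 of the 15 alternative settings. The 19 named genes past the threshold kept their direction in all 15, and from 1 to 19 of them stayed past it.

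No filter on low values gave 10 genes (8 at least 2-fold, 14 probe sets), and the filter at the 60th percentile 97 (96, 179 probe sets), 27 of them among the 28. Median centring gave 155 genes, all at least 2-fold (311 probe sets, 54 genes higher and 101 lower against 6 and 22), and array weights 385 (289, 958 probe sets, 125 higher and 260 lower), and both held all 28. Quantile normalization gave 35 genes (11 higher and 24 lower), the intensity trend with robust variance 40, the mean of probe sets 24, leaving out probe sets prone to cross-hybridization 31, and leaving out normal replicate 2 gave 20. Centring moved the median difference of all genes from 0.03 to 0.26. The count of genes whose groups do not overlap, 4203, has no p-value and an expected share of 10% by chance. It was 3021 for genes above background on some array, an alternative chosen after seeing the data. Leave-one-out counts ran from 4 to 82 genes, at either size threshold, and from 7 to 137 probe sets. The cause was not tested.

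Camera called 7 lists in each of the 15 settings, the leukocyte list in place of the protease list without normal replicate 3, tumour replicate 2 or tumour replicate 3. It called 0 with an estimated correlation, as did fry. The smallest adjusted p by fry was 0.0628.

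The replicate number as a block gave 46 genes (46 at least 2-fold, 53 probe sets), 18 of them among the 28. Deviations of same-numbered arrays correlated at 0.19, 0.33 and -0.0038, and those of differently numbered arrays at -0.37 to 0.13. With 3 arrays per group these values cannot decide whether the numbers pair the arrays.

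Some values that had not passed changed sign. Flt4 was -0.0054 with quantile normalization and -0.28 with array weights, which also gave Prox1 -0.091, the lymphatic list -0.052 and vessel growth -0.16. Blood vascular genes were -0.00010 with quantile normalization and -0.052 with the mean of probe sets, pericyte genes -0.094 with the 60th percentile filter, and dissociation stress genes 0.067 with median centring. Leave-one-out ranges crossed 0 for Flt4 (-0.21 to 0.22), Ptprc (-0.016 to 1.41), Pdpn (-0.080 to 0.33), Cd68 (-2.50 to 0.53), and the vessel growth (-0.17 to 0.17), pericyte (-0.22 to 0.13), leukocyte (-0.12 to 0.80) and skeletal muscle (-0.014 to 0.11) lists. The cause was not tested.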

Other observations

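The tests of normalization, of the share of lymphatic cells, of the Mycn neighbours and of the Mycn probe sets were chosen after the result was seen, and the second fibroblast list, the Hox genes and the other splits before.

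Guidance and growth factor genes went in opposite directions within their lists. Adjusted over the list alone, Pdgfb (3.50), Sema3d (3.18), Lepr (2.66), Angpt2 (1.51) and Unc5b (1.49) were higher in tumour LEC, and Sema3c (at least 37.0-fold) and Robo1 (at least 3.19-fold), both at background in tumour LEC, and Pdgfc (-3.37), Ntn1 (at least 2.80-fold, with 2 tumour arrays at background) and Efnb1 (-0.91) lower. In the TGF-beta and BMP list Tgfb2 (1.73), Tgfb3 (1.33), Eng (1.70), Bmpr2 (0.96) and Smad1 (0.68) were higher, and Inhba (-3.54), Bmpr1a (-3.88), Tgfbr1 (-1.12), Smad3 (-0.87) and Grem1 (at least 13.7-fold, at background in tumour LEC) lower. At junctions, Magi3 (1.98) and F11r (1.40) were higher and Jam2 (at least 7.43-fold, with 2 tumour arrays at background) lower. Of the 10 lower genes of the first 2 lists, 9 were highest in normal replicate 1 among the normal arrays, as were the fibroblast markers (median deviation 3.86), and so was Jam2. Of these genes, Sema3c and Grem1 alone passed over all genes. Apart from Unc5b, Sema3c, Eng and Grem1, they were named after their values were seen.

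The lower fibroblast and matrix genes in tumour LEC may reflect fibroblasts in the normal dermal preparations. A second fibroblast list of 19 measured genes, none of them in the other lists, had a median of -1.41 with 17 lower, and 18 were highest among the normal arrays in normal replicate 1. Col1a2 read 14.29 on that array, and the LYVE-1 selection should have removed such cells. Under quantile normalization and median centring the median of the first fibroblast list stayed at -3.39 or lower. The median of all genes moved only to 0.05 and 0.26, so a shift of whole arrays is too small to account for the list. The deposited values were already normalized, and their background correction was not tested by these steps. Without normal replicate 1 the medians were -2.98 for the first list and -0.70 for the second. On some tumour array 18 of the 24 genes of the first list were above background. Among these, Col1a2, Col3a1, Cdh11 and Pdgfrb were at background on 2 tumour arrays, and Lox, Prrx1, Twist1, Twist2 and Fbln1 on 1. Which cells gave the remaining signal is not known. Lower expression by the tumour LEC themselves stays open and untested.

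The higher pan-endothelial genes could have the same source, as a lower share of lymphatic endothelial cells in the normal arrays. Dilution would move lymphatic genes alike. Among genes with a mean above 6 the pan-endothelial median was 1.01 (25 genes) and the lymphatic median 0.40 (13 genes). Exchanging genes between both lists gave a permutation p of 0.0141, two-sided, and that first test would have argued against dilution. Genes that vary together across the same arrays are not independent, so the permutation p-values do not measure the spread between arrays. The test was then repeated without Pdpn, Nr2f2 and Foxc2, which fibroblasts also express, a change made after 0.0141 had been seen, and gave a lymphatic median of 0.51 (10 genes) and a permutation p of 0.0664. The outcome depends on which lymphatic genes are counted, so dilution and a change in the endothelial cells cannot be told apart here.

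The Mycn signal was the largest difference of the comparison. A gain of the surrounding chromosomal region would raise its neighbours, but the 6 nearest genes with a mean above 6, Rdh14, Smc6, Cyria, Ddx1, Nbas and Trib2, had a median difference of -0.11, the highest being Cyria at 1.29. A second probe set also differed, by 2.12 with separated groups (limma, adjusted p = 0.112 over probe sets). The direction was thus not seen on a single probe set only. The size of 10.47 was, so an error of that probe set stays open for the size. The sizes of 10.47, 2.12 and 0.13 are unequal, so a transcript that holds part of the gene stays a candidate explanation. A gain of Mycn alone and induction in tumour LEC stay candidates too, and none of these was tested. Tumour cells left in the cultures after the EDTA step were not tested as a source of the signal either.

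Tail skin lies at the posterior end of the body, so a hypothesis was that Hox genes of paralogue groups 9 to 13 would be lower in tumour LEC. The median difference of the 7 measured was 0.15, which by the bound fixed beforehand, -0.5, would have argued against it. That bound took no account of genes without signal: only 4 were above background, and these went both ways, with Hoxa9 at -1.30 and Hoxd10 at 1.25, so after the values were seen the test was taken to decide nothing. Hox genes of groups 1 to 8 had a median of 0.69 over 13 genes, with Hoxb6 at 1.95, Hoxb3 at 1.89 and Hoxb5 at 1.76, none past the threshold.

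There are 10 splits of the 6 arrays into groups of 3, too few for a share under 0.05. The real split gave 28 genes, 28 at least 2-fold and 60 probe sets, each as large in 1 of the 10 splits, the real one, and the highest other split gave 0 of each. Every other split mixes tumour and normal arrays, so the group difference widens the spread there, and its 0 does not show what chance gives. For gene lists the real split gave 7, 5 of the 10 splits gave as many, and the highest other gave 11. Camera at the preset correlation thus called more lists in some splits that mix the groups. Its calls alone do not set tumour apart from normal LEC.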
